A study of Mus musculus with 6 samples.

How the data were processed

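RNA of 6 heart samples from male mice aged 2 months was measured, 2 samples in each of 3 groups (RKIP-transgenic, GRK-Inh-transgenic and B6 control). Per the labels, total RNA was isolated with a column kit, and biotin-labelled cRNA was hybridised to Affymetrix mouse arrays. The authors deposited an intensity for each probe set, a linear signal that they had computed and scaled with GCOS according to the submitters' processing notes, which give no version. The deposited values had the same 2% trimmed mean of 300.002 on every array, which was checked on the values. Groups and replicate numbers were read from the sample titles, and no sample was left out. Arrays give no counts, so their number limits the precision: the median SE of a log2 fold change was 0.115.

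The table held 45101 probe sets, of which 64 control probe sets were set aside. The gene table used gave 34945 probe sets a single gene symbol, 932 several symbols and 9160 none, and 34754 of its 35890 probe sets had a gene identifier that matched the RefSeq gene table. Probe sets with several symbols or none were left out of the gene-level tests and tested apart. Members of the fixed lists and fixed genes without a probe set in that table were not analysed here. No coordinates are given, because the table names no genome build. Signals were transformed as log2 of the signal plus 50, without further normalization. The probe set with the highest mean represented each of the 18193 genes, and the 11254 genes whose mean log2 value was at least 6.65, the median over all non-control probe sets (a signal of 50.2), were tested.

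Differences were tested in R 4.3.3 with limma 3.58.1, in a single linear model over the 6 arrays with 3 residual degrees of freedom and with variances moderated along a trend with the mean level (7.60 prior degrees of freedom). A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, in each of 3 comparisons: RKIP-transgenic against control, GRK-Inh-transgenic against control, and RKIP-transgenic against GRK-Inh-transgenic. Values are log2 fold changes with the model's SE, or mean signals with their SD over 2 arrays. The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule named, per comparison, the 12 genes with the largest rise and the 12 with the largest fall among called genes whose arrays did not overlap, up to 6 called members of each list or, where none was called, up to 2 of highest signal, the 10 genes of largest shared change per direction, and always Pebp1, Nppa, Nppb, Myh6, Myh7 and Acta1. It gave 237 genes.

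Gene lists numbered 36, of which 20 were pathways and 16 were markers of cell types, neighbouring tissue or sex, and 33 with at least 3 tested members were tested. The camera test with a preset correlation of 0.01 between genes compared each list with the other genes. It was repeated with the correlation estimated from the data, where camera uses only the 3 residual degrees of freedom and p-values stay larger. The fry test asked whether a list's genes moved one way on balance, without a comparison with other genes. List tests were adjusted over the 33 lists of a comparison, and members were also adjusted over the list alone. The overlap of the lines was compared with the product of the counts divided by the genes tested, and with 100 simulations of unchanged groups that shared their controls. Contrasts of small sets of genes used exact permutation tests, two-sided.

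The procedure was tested on simulated data for the RKIP-transgenic against control comparison, with 11254 genes. Of the genes changed by 0.5 on the log2 scale it called 54.8%, by 1 it called 93.8% and by 2 it called 100%, and 14 of its 177 calls were of unchanged genes. A list shifted by 0.3 had a camera adjusted p of 2.3e-43, and 0.0274 with an estimated correlation, and 0 other lists were called. The simulated genes were drawn independently. These list results therefore do not show how often camera calls an unchanged list whose genes are correlated. The alternatives were quantile normalization, a shift of the arrays to one median, offsets of 16 and 200, no filter or a filter at the 75th percentile, all probe sets tested one by one, a variance without trend or with robust moderation, only the arrays of the compared groups, the replicate number as a block, other thresholds, other list tests, and each array left out in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.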

Results

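Gene expression was measured in heart RNA of male mice aged 2 months on 6 Affymetrix mouse arrays, each with 45101 probe sets. The labels place 2 arrays in each of 3 groups. RKIP-transgenic mice carried a transgene for RKIP, an inhibitor of the kinase RAF and of G-protein-coupled receptor kinases, behind the alpha-MHC promoter. GRK-Inh-transgenic mice expressed a peptide inhibitor of the receptor kinases in the myocardium, and B6 mice served as controls. All groups are labelled with a B6 strain background. Median signals per array lay between 50.4 and 55.2 after the authors' scaling to a trimmed mean of 300.002. Over the 11254 genes tested, the SD of the log2 difference between arrays was 0.206 to 0.209 within groups and 0.275 to 0.314 between groups. The labels do not say whether the arrays of a group came from separate animals, so the p-values measure only the spread between these samples, which can be technical. The ratio of the 3' to the 5' actin control signal was between 2.92 and 3.03 on the 4 arrays of the transgenic groups and higher on the control arrays, at 3.25 and 3.11. The Y-linked gene Eif2s3y gave a signal of 1137 to 1838 on every array, and no probe set of Xist exceeded 64.4. Eif2s3y was called higher in RKIP-transgenic than in control hearts (log2 fold change 0.57 ± 0.079, adjusted p = 0.00111). It was also called higher in RKIP-transgenic than in GRK-Inh-transgenic hearts (0.45 ± 0.079, adjusted p = 0.00612), a call lost with a variance without trend.

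Pebp1, the mouse gene for RKIP, was not called in any of the 3 comparisons. Its probe set of higher signal gave 9121 ± 27.4 in RKIP-transgenic, 9187 ± 153 in GRK-Inh-transgenic and 9029 ± 372 in control hearts (mean signal ± SD, n = 2). The log2 fold change between RKIP-transgenic and control hearts was 0.015 ± 0.041 (± SE, adjusted p = 0.866). The other probe set lay between 5284 and 5912 on the 6 arrays. This does not test the transgene, since a transgene of another species, or one lacking the probed 3' part, would not be seen by these probes. The group is called RKIP-labelled below for that reason.

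The comparison of RKIP-labelled with B6 control hearts addresses which heart transcripts go with the RKIP transgene. Nppb, which encodes the natriuretic peptide BNP, rose from 5435 ± 86.2 to 12018 ± 236 (mean signal ± SD, n = 2 per group). The skeletal actin gene Acta1 and the beta-myosin gene Myh7, both of the fetal heart programme, rose by 1.28 ± 0.057 and 0.85 ± 0.079 on the log2 scale (± SE). Nppa (-0.062 ± 0.032, adjusted p = 0.261) and the adult myosin gene Myh6 (-0.064 ± 0.035, adjusted p = 0.289) did not pass. On the 6 arrays Myh6 had signals of 35906 to 39466, close to the arrays' highest signals (37546 to 41679). Whether signals so high can still show a change was not tested. Myot, the gene of a Z-disc protein, had the largest rise past the threshold, from 538 ± 58.6 to 2184 ± 66.6 (log2 fold change 1.93 ± 0.076, adjusted p = 2.9e-07). The transferrin receptor gene Tfrc had the largest fall, from 7403 ± 142 to 1754 ± 59.0 (log2 fold change -2.05 ± 0.053, adjusted p = 9.9e-09). The retinoid genes Cyp26b1 and Lrat fell by 1.77 and 1.40 on the log2 scale, to signals of 40.5 and 44.2, below the filter level of 50.2. The size of both falls depended on the offset, with log2 fold changes of -2.29 to -0.93 and -1.85 to -0.70 over the alternatives.

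In all, 599 genes rose and 620 fell among 11254 tested, 10.8% of them, and 21 rose and 20 fell at least 2-fold. Of the list of hypertrophy and fetal genes, 8 of 15 members rose and 2 fell (9 and 2 adjusted over the list alone). The list's median log2 fold change was 0.24 (camera adjusted p = 0.000389, and adjusted p = 0.202 with an estimated correlation). Its falling members included Ccn2, a matricellular growth factor gene, at -0.84 ± 0.047. Extracellular matrix genes fell as a group: 1 of 27 members rose and 14 fell (1 and 16 adjusted over the list alone). The members' median log2 fold change was -0.48 (camera adjusted p = 1.7e-11, and adjusted p = 0.168 with an estimated correlation). With all probe sets tested one by one the median was -0.31. Col1a1 fell from 646 ± 0.564 to 270.4 ± 16.2, Col3a1 from 12474 ± 829 to 6088 ± 31.4, and the basement membrane gene Col4a1 by 1.25 on the log2 scale. Fibroblast markers fell beside them: 0 of 12 members rose and 7 fell (0 and 12 adjusted over the list alone). The median over the list was -0.37 (camera adjusted p = 1.6e-10, and adjusted p = 0.168 with an estimated correlation). Of these markers, 3 are also in the matrix list. Markers of smooth muscle and pericytes were lower too: 0 of 12 members rose and 6 fell (1 and 6 adjusted over the list alone). Over these genes the median was -0.19 (camera adjusted p = 0.00750, and adjusted p = 0.334 with an estimated correlation). Acta2 fell by 0.50 on the log2 scale. That list call was lost without RKIP array 1 and with a variance without trend (adjusted p 0.000883 to 0.0764 over the alternatives).

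Genes of fuel use moved in both directions in the RKIP-labelled hearts. Of the fatty acid oxidation genes, 6 of 26 members rose and 3 fell (8 and 3 adjusted over the list alone). Angptl4, Ucp3 and Pdk4, which respond to fatty acids, fell by 1.30, 1.29 and 0.89 on the log2 scale, whereas Hadha, the gene of a beta-oxidation enzyme, rose (0.25 ± 0.053), a call lost without RKIP array 2, without B6 array 1 and with a variance without trend (adjusted p 0.00913 to 0.149 over the alternatives). The median of this list was 0.066 and its mean -0.039. For it camera gave a direction upwards without passing (adjusted p = 0.216), and fry gave a direction downwards (adjusted p = 0.0158). Outside the list the ketone enzyme gene Bdh1 (1.39 ± 0.073) and the GABA transaminase gene Abat (1.76 ± 0.14) rose. The glucose transporter gene Slc2a1 and the glycolysis regulator gene Pfkfb2 rose by 0.65 and 1.06 on the log2 scale. Of the glycolysis genes, 5 of 18 members rose and 1 fell (6 and 4 adjusted over the list alone), and the list did not pass by camera (adjusted p = 0.0913, and fry adjusted p = 0.0327, upwards). Of the lipid synthesis genes, 4 of 20 members rose and 8 fell (6 and 9 adjusted over the list alone). The desaturase gene Scd1 fell (-0.63 ± 0.093), and the list did not pass by camera (adjusted p = 0.216, and fry adjusted p = 0.0296, downwards). White adipocyte markers were lower beside these genes: 1 of 7 members rose and 3 fell (1 and 4 adjusted over the list alone). The list had a median of -0.34 (camera adjusted p = 0.00750, and adjusted p = 0.279 with an estimated correlation). That call was lost with a filter at the 75th percentile (adjusted p 4.1e-05 to 0.267 over the alternatives). Car3 fell from 3312 ± 142 to 1046 ± 38.3 and Adipoq from 297 ± 13.7 to 84.8 ± 5.63, while Fabp4, also expressed in heart endothelium, fell by 0.24 on the log2 scale, a call lost with a variance without trend (adjusted p 0.00247 to 0.141).

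Interferon-stimulated genes were lower in the RKIP-labelled hearts, where 0 of 22 members rose and 6 fell (0 and 9 adjusted over the list alone). The list's median log2 fold change was -0.27 (camera adjusted p = 3.8e-06, and adjusted p = 0.168 with an estimated correlation). Rsad2, Ifi27l2a and B2m fell by 0.70, 0.68 and 0.36 on the log2 scale. The call of B2m was lost with a variance without trend (adjusted p 0.000165 to 0.0588). Genes of the NRF2 response to oxidants were higher: 5 of 14 members rose and 0 fell (6 and 0 adjusted over the list alone). The members' median log2 fold change was 0.20 (camera adjusted p = 0.00209, and adjusted p = 0.279 with an estimated correlation). The glutathione transferase genes Gstm1 (0.74 ± 0.10) and Gsta4 (0.38 ± 0.067) rose, calls that were lost with that variance (adjusted p 0.00106 to 0.0588 and 0.00434 to 0.0947). Of the genes of the unfolded protein response, 5 of 20 members rose and 1 fell (8 and 3 adjusted over the list alone). The median over the list was 0.17 (camera adjusted p = 0.0210, and adjusted p = 0.334 with an estimated correlation). Its chaperone genes Dnajb9 and Hspa5 rose by 0.59 and 0.19 on the log2 scale, and the call of Hspa5 was lost with that variance (adjusted p 0.00315 to 0.172). Without RKIP array 1 the median was 0.11. The list call was lost without RKIP array 2, without B6 array 2 and with a variance without trend (adjusted p 0.0143 to 0.0640 over the alternatives). Of the list of RKIP, receptor kinase and receptor signalling genes, 1 of 19 members rose and 2 fell (1 and 4 adjusted over the list alone). The list did not pass by camera (adjusted p = 0.130) and passed by fry (fry adjusted p = 0.0150, downwards). Grk5 rose (0.54 ± 0.087) and Rgs2, a brake on Gq signalling, fell (-0.72 ± 0.061). Of the RAF-MEK-ERK genes, 0 of 13 members rose and 1 fell (0 and 1 adjusted over the list alone), camera adjusted p = 0.729. The member that fell was the ERK feedback gene Dusp6, at -0.25 (adjusted p = 0.0363 over all genes). Of the immediate early genes, 2 of 19 members rose and 2 fell (2 and 3 adjusted over the list alone), with Nr4a1 up (1.00 ± 0.13) and Egr1 (-1.07 ± 0.076) and Dusp1 (-0.61 ± 0.071) down. That list did not pass (adjusted p = 0.466). Of 33 lists, 25 did not pass by camera (adjusted p 0.0534 to 0.991). Leaving out 1 array gave 688 genes without RKIP array 1, 737 without RKIP array 2, 621 without B6 array 1 and 628 without B6 array 2. A variance without trend gave 297 genes.

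**Figure D1:**
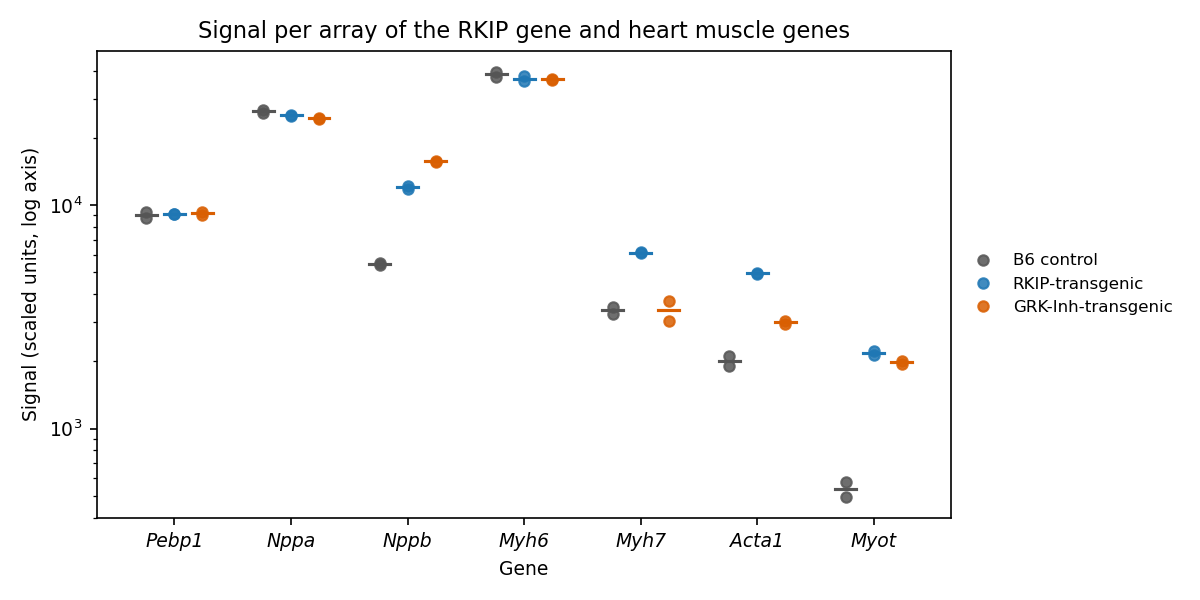
Signals (linear units after the authors' scaling, log axis) of Pebp1 and 6 heart muscle genes on each of the 6 arrays, with the group means as bars. Nppb and Myot lie higher in both transgenic groups than in the controls, at mean signals of 12018 and 2184 in RKIP-labelled against 5435 and 538 in control hearts, and Myh7 lies higher in the RKIP-labelled hearts, at 6136.

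The comparison of GRK-Inh-transgenic with B6 control hearts addresses the transcripts that go with inhibition of receptor kinases by a peptide. The heat shock protein gene Hspa1b rose from 326 ± 5.99 to 3186 ± 2.08 (mean signal ± SD, n = 2 per group), a log2 fold change of 3.10 ± 0.087 (± SE, adjusted p = 8.0e-09). The values of this gene and its near-identical paralog Hspa1a cannot be assigned to either with certainty. The immediate early gene Fos rose from 90.6 ± 25.0 to 859 ± 29.7 (log2 fold change 2.70 ± 0.15, adjusted p = 1.6e-06), and the size of this rise depended on the offset (1.87 to 3.06 over the alternatives). Abra, which couples actin to serum response factor, and Tnfrsf12a, the receptor of the cytokine TWEAK, rose by 2.38 ± 0.092 and 2.14 ± 0.076 on the log2 scale. Nppb rose to 15731 ± 62.2 (1.52 ± 0.037) and Acta1 by 0.56 ± 0.057. Myh7 (-0.0023 ± 0.079, adjusted p = 0.989), Nppa (-0.10 ± 0.032, adjusted p = 0.0609) and Myh6 (-0.074 ± 0.035, adjusted p = 0.198) did not pass. Tfrc fell to 1195 ± 21.3 (log2 fold change -2.58 ± 0.053, adjusted p = 8.5e-10).

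In this comparison 659 genes rose and 818 fell, 13.1% of those tested, and 38 rose and 31 fell at least 2-fold. Of the heat shock genes, 10 of 13 members rose and 0 fell (13 and 0 adjusted over the list alone). Over these genes the median was 0.75 (camera adjusted p = 6.7e-20, and adjusted p = 0.0571 with an estimated correlation). Hsph1 (1.40 ± 0.085), Hsp90aa1 (1.32 ± 0.057) and the small chaperone gene Hspb1 (0.98 ± 0.051) were among them. Of the immediate early genes, 13 of 19 members rose and 0 fell (15 and 0 adjusted over the list alone). The list had a median of 0.75 (camera adjusted p = 1.4e-17, and adjusted p = 0.0571 with an estimated correlation). Egr1 (1.47 ± 0.076) and the nuclear receptor gene Nr4a3 (1.79 ± 0.19, 0.99 to 2.26 over the alternatives, depending on the offset) rose. Of the unfolded protein response genes, 11 of 20 members rose and 1 fell (12 and 1 adjusted over the list alone). The list's median log2 fold change was 0.44 (camera adjusted p = 1.2e-09, and adjusted p = 0.0650 with an estimated correlation). The endoplasmic reticulum genes Creld2, Sdf2l1 and Hspa5 rose by 1.14, 0.96 and 0.52 on the log2 scale, and Chac1, a target of the integrated stress response, fell by 1.33 to a signal of 76.5 (log2 fold change -1.65 to -0.74 over the alternatives, depending on the offset). Of the hypertrophy genes, 11 of 15 members rose and 0 fell (11 and 1 adjusted over the list alone). The members' median log2 fold change was 0.52 (camera adjusted p = 4.0e-13, and adjusted p = 0.0571 with an estimated correlation). With an offset of 200 the median was 0.34. The calcineurin regulator gene Rcan1 (1.27 ± 0.083) and Ccn2 (1.14 ± 0.047) rose. Of the RAF-MEK-ERK genes, 2 of 13 members rose and 2 fell (2 and 2 adjusted over the list alone), with Dusp6, a feedback gene of ERK, up (0.41 ± 0.066) and Phlda1 down (-0.58 ± 0.051). The list did not pass (adjusted p = 0.798). Of the receptor signalling genes, 2 of 19 members rose and 3 fell (2 and 4 adjusted over the list alone), and the list did not pass by camera (adjusted p = 0.251) but passed by fry (fry adjusted p = 0.0171, downwards), with Grk5 up (0.49 ± 0.087) and Rgs2 down (-0.37 ± 0.061).

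**Figure D2:**
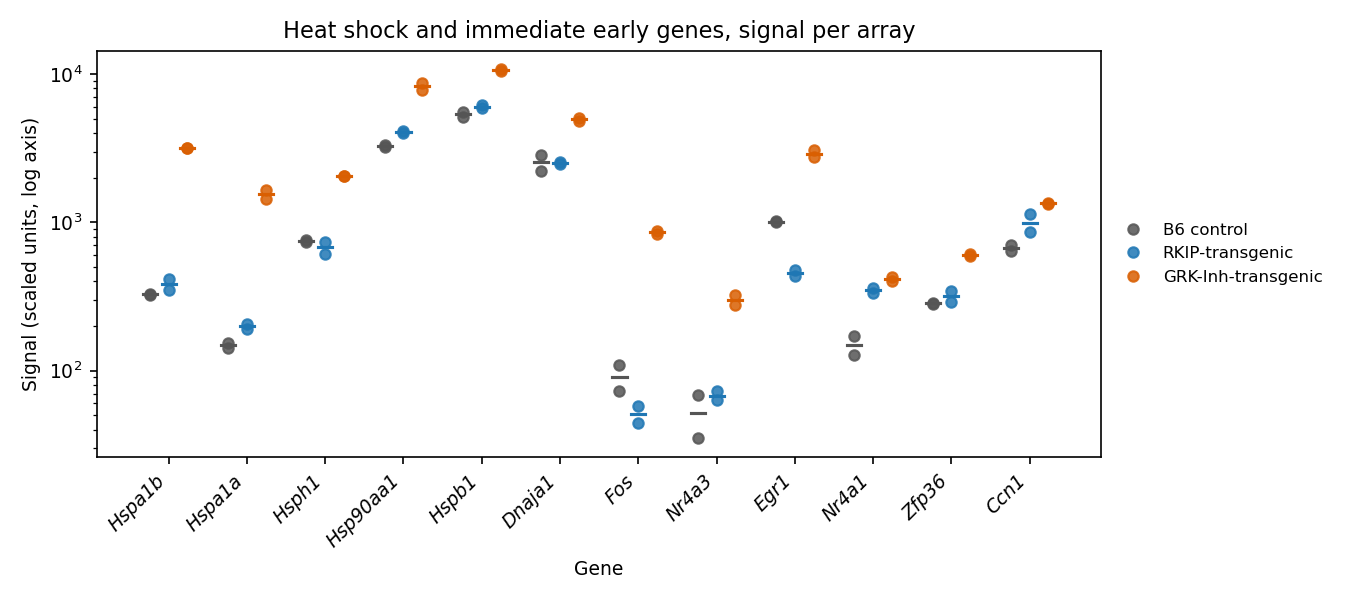
Signals (linear units after the authors' scaling, log axis) of 6 heat shock genes and 6 immediate early genes on each of the 6 arrays, with the group means as bars. In GRK-Inh hearts the mean signal of Hspa1b was 3186 and that of Fos 859, against 326 and 90.6 in controls and 381 and 50.9 in RKIP-labelled hearts.

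Matrix genes were lower in the GRK-Inh hearts, where 1 of 27 members rose and 15 fell (1 and 18 adjusted over the list alone). The median over the list was -0.49 (camera adjusted p = 5.0e-10, and adjusted p = 0.112 with an estimated correlation). Col1a1 fell to 268 ± 38.7 and Col3a1 to 6172 ± 219, while Timp4, a protease inhibitor gene, rose from 807 ± 28.5 to 2689 ± 6.42. Fibroblast markers fell with them: 0 of 12 members rose and 10 fell (0 and 12 adjusted over the list alone). Over these genes the median was -0.48 (camera adjusted p = 8.7e-12, and adjusted p = 0.0650 with an estimated correlation). Lum (-0.74 ± 0.055) and Fbln1 (-0.57 ± 0.078) were among them. Smooth muscle and pericyte markers gave 5 lower members of 12 (1 higher and 6 lower adjusted over the list alone). The list had a median of -0.20 (camera adjusted p = 0.0483, and adjusted p = 0.436 with an estimated correlation). Macrophage markers gave 3 lower of 13 (3 adjusted over the list alone). The list's median log2 fold change was -0.15 (camera adjusted p = 0.0302, and adjusted p = 0.436 with an estimated correlation). The smooth muscle call was lost without GRK-Inh array 1, without B6 array 1 and with a variance without trend (adjusted p 0.0128 to 0.273 over the alternatives). The macrophage call was lost without GRK-Inh array 1, without B6 array 2 and with that variance (adjusted p 0.00315 to 0.0933 over the alternatives). Of 3 lymphocyte markers with a tested probe set, 2 rose (3 adjusted over the list alone). The members' median log2 fold change was 1.30 (camera adjusted p = 0.000375, and adjusted p = 0.117 with an estimated correlation). Without a filter on dim genes the median was 0.24 (adjusted p = 0.0224). Of 14 fixed markers only these 3 were tested, and a rise in 1 group can bring a gene past the filter. The immunoglobulin genes Ighm and Jchain rose from 172 and 49.1 to 843 and 198.

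Of the fatty acid oxidation genes, 8 of 26 members rose and 2 fell (11 and 3 adjusted over the list alone) in the GRK-Inh hearts. The median over the list was 0.086 (camera adjusted p = 0.00108, and adjusted p = 0.117 with an estimated correlation). With the arrays shifted to one median it was 0.13. The regulator genes Ppargc1a (0.65 ± 0.059) and Ppara (0.55 ± 0.077) and the thioesterase gene Acot1 (0.62 ± 0.11) rose, while Angptl4 (-0.87 ± 0.10) and Ucp3 (-1.12 ± 0.10) fell. Subunits of oxidative phosphorylation had a median of -0.063 (camera adjusted p = 0.0302, and adjusted p = 0.619 with an estimated correlation). Of this list, 1 of 43 members rose and 3 fell (1 and 1 adjusted over the list alone). That call was lost after quantile normalization, after shifting the arrays to one median, with a variance without trend, and without GRK-Inh array 1, GRK-Inh array 2 or B6 array 1 (adjusted p 0.00626 to 0.922 over the alternatives). Clock genes moved in opposite directions: 3 of 15 members rose and 5 fell (3 and 5 adjusted over the list alone), with the list not past camera's threshold (adjusted p = 0.415, and fry adjusted p = 0.0251, downwards). Arntl rose by 1.14 (0.53 to 1.57 over the alternatives, depending on the offset) and Nfil3 by 0.59 on the log2 scale. Dbp fell from 8184 ± 202 to 3797 ± 55.5 and Per3 by 1.06 on the log2 scale. Channel genes moved both ways as well: 4 of 19 members rose and 5 fell (4 and 7 adjusted over the list alone), list adjusted p = 0.667. Kcna5 rose (0.59 ± 0.091) and Kcnh2 fell (-0.49 ± 0.088). Zbtb16, a transcription factor gene, rose from 660.3 ± 133 to 2384 ± 5.76, and Wdfy1 fell from 511 ± 38.3 to 127 ± 14.3. The labels name no B6 substrain, and strain variants were not tested. Of 33 lists, 22 did not pass by camera (adjusted p 0.0709 to 0.960). Leaving out 1 array gave 896 genes without GRK-Inh array 1, 908 without GRK-Inh array 2, 911 without B6 array 1 and 921 without B6 array 2. A variance without trend gave 731 genes.

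**Figure D3:**
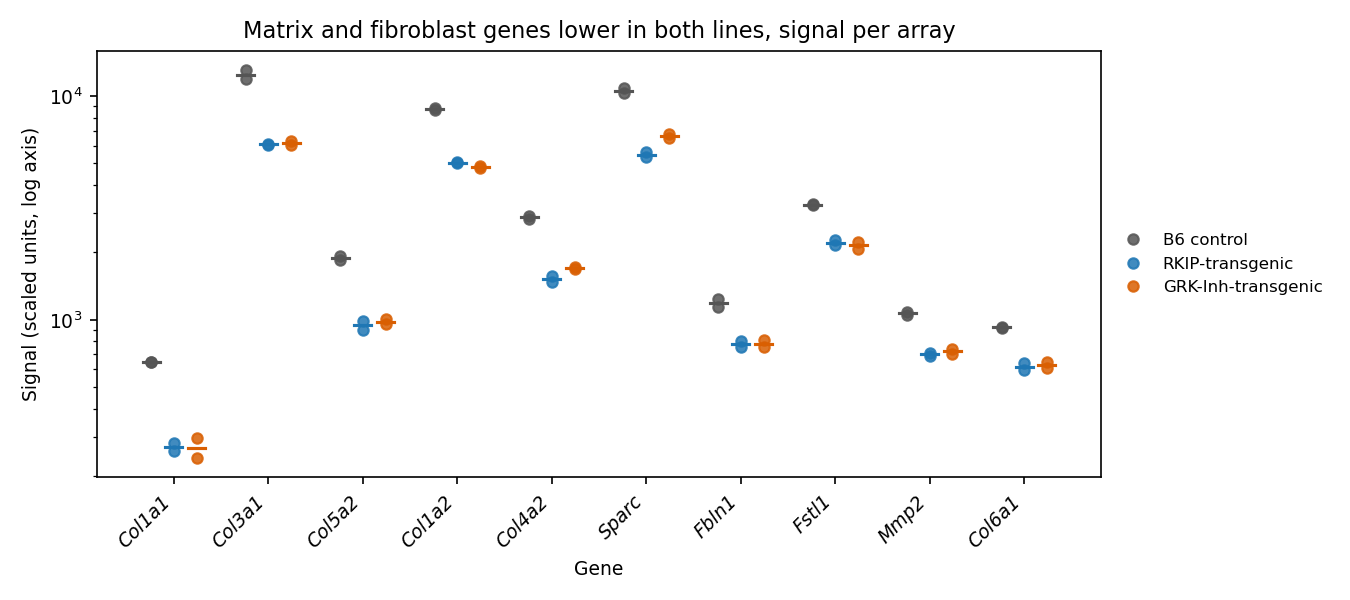
Signals (linear units after the authors' scaling, log axis) of 10 matrix and fibroblast genes on each of the 6 arrays, with the group means as bars. Col3a1 had mean signals of 6088 in RKIP-labelled, 6172 in GRK-Inh and 12474 in control hearts.

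The transgenic lines shared many of their differences from the controls. In both lines 287 genes rose and 303 fell, against 35.1 and 45.1 if the calls were independent (the product of the counts divided by the genes tested), and 31 genes were called in opposite directions, against 79.8. Both lines were compared with the same 2 control arrays, so unchanged groups that shared them were simulated 100 times. These gave 0.07 genes called in the same direction on average and 2 at most, a count that the threshold keeps near 0. Across genes, which are not independent replicates, the log2 fold changes of the lines had a Pearson r of 0.557 and a Spearman rho of 0.543, against means of 0.50 and 0.467 in the simulations. Their covariance was 0.0369, against a simulated mean of 0.00893 and a highest simulated value of 0.00988. The simulations used the spread between arrays of a group, which can be technical, so they leave out differences between control animals if the arrays of a group share an animal. The 2 controls cannot be divided into groups of 2, so part of the excess can still come from the shared controls. Leaving out 1 array gave 386 shared genes without RKIP array 1, 342 without B6 array 1 and 336 without B6 array 2, and a variance without trend gave 161.

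Among the shared genes, Myot rose by 1.93 ± 0.076 in the RKIP-labelled and 1.79 ± 0.076 in the GRK-Inh hearts on the log2 scale, and the carboxypeptidase-like gene Cpxm2 rose to 650.5 and 663 from 198. Prune2 rose to 1435 and 1388 from 508, the sodium channel subunit gene Scn4b to 308 and 272 from 94.9, and the amylase gene Amy1 to 333 and 260.1 from 107. The shared falls included Tfrc, Cyp26b1 and Lrat, the water channel gene Aqp4 (-1.29 and -1.48), the growth factor gene Igf2 (-1.19 and -1.28) and the apelin receptor gene Aplnr (-1.02 and -1.07). Of the matrix and fibroblast lists together, 17 genes fell in both lines, and 5 of the 33 lists passed in both lines. With an estimated correlation none of these 5 passed in either line (adjusted p of 0.0571 and above). The actin ratio given above was also higher in both controls (3.25 and 3.11) than on the 4 transgenic arrays (2.92 to 3.03). Of the matrix list, 1 of 27 members was higher and 4 lower (1 and 4 adjusted over the list alone) in RKIP-labelled than in GRK-Inh hearts. Its median log2 difference was -0.025 (camera adjusted p = 0.118, and fry adjusted p = 0.0499, downwards), and Col4a1 differed by -0.75 ± 0.054 (adjusted p = 1.3e-05). The fibroblast markers did not pass between the lines (median 0.032, camera adjusted p = 0.154). The matrix list passed by camera in that comparison without GRK-Inh array 2 (adjusted p = 0.0291, range 0.0291 to 0.347 over the alternatives).

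**Figure D4:**
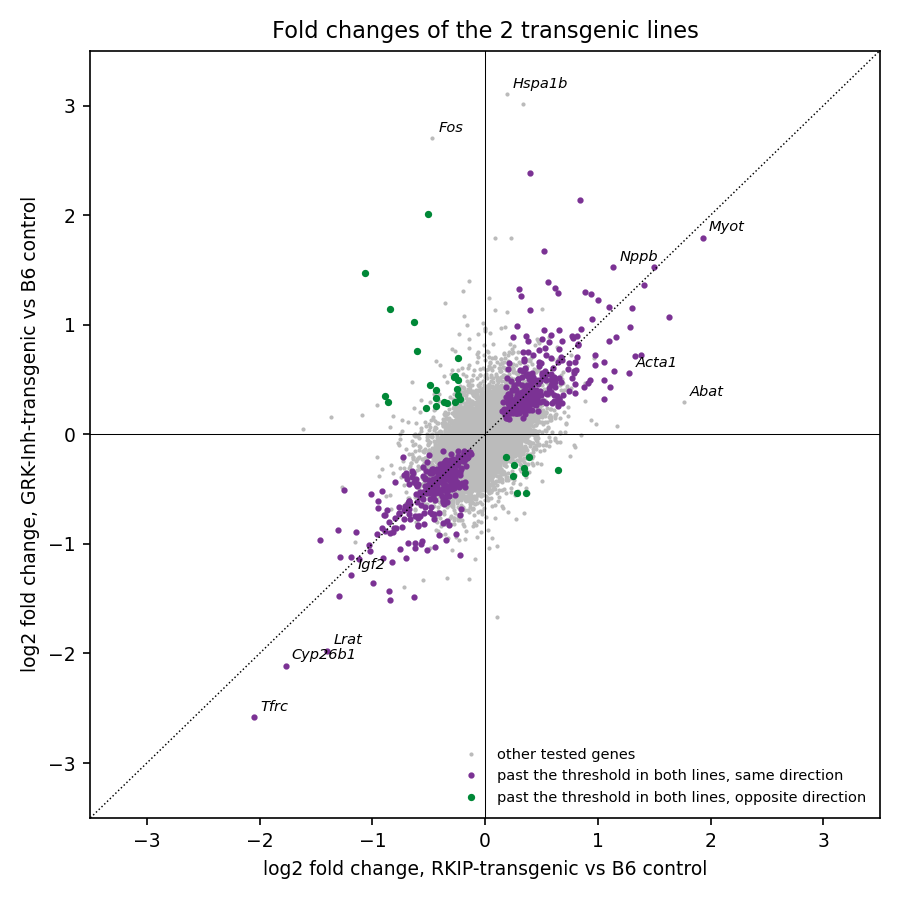
Log2 fold change against control of each of the 11254 genes in RKIP-labelled hearts (horizontal axis) and GRK-Inh hearts (vertical axis), coloured by the calls in the comparisons. The genes called in the same direction number 590 and those called in opposite directions 31, and both axes use the same 2 control arrays.

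The direct comparison of RKIP-labelled with GRK-Inh hearts addresses what separates the lines and does not use the controls as a reference. The signal of Fos was 50.9 ± 9.15 in RKIP-labelled and 859 ± 29.7 in GRK-Inh hearts (mean ± SD, n = 2 per group), a log2 difference of -3.17 ± 0.15 (± SE, adjusted p = 6.1e-07). The RKIP-labelled signal lies at the filter level, and the size of this difference depended on the offset (-3.72 to -2.08 over the alternatives). That of Egr1 was 457 ± 32.3 and 2900.4 ± 212 (-2.54 ± 0.076, adjusted p = 1.6e-08). Ccn2 and the lipid desaturase gene Scd1 were lower in the RKIP-labelled hearts, at log2 differences of -1.98 and -1.66. Myh7 was higher in the RKIP-labelled hearts (0.85 ± 0.079, adjusted p = 8.7e-05), as was Acta1 (0.72 ± 0.057). Nppb was lower (-0.39 ± 0.037, adjusted p = 0.000108, a call lost with a variance without trend). Dnm2, the gene of a membrane-severing GTPase, was higher in the RKIP-labelled hearts (626 ± 21.1 against 268 ± 28.6).

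Between the lines 503 genes were higher and 490 lower in the RKIP-labelled hearts, 8.82% of those tested, and 10 were higher and 34 lower at least 2-fold. Of the heat shock genes, 0 of 13 members were higher and 11 lower (0 and 13 adjusted over the list alone). Over these genes the median was -0.61 (camera adjusted p = 2.2e-23, and adjusted p = 0.0634 with an estimated correlation). Of the immediate early genes, 0 of 19 members were higher and 14 lower (0 and 16 adjusted over the list alone). The list had a median of -0.73 (camera adjusted p = 1.1e-20, and adjusted p = 0.0674 with an estimated correlation). Of the unfolded protein response genes, 1 of 20 members was higher and 9 lower (2 and 11 adjusted over the list alone). The list's median log2 fold change was -0.24 (camera adjusted p = 1.4e-05, and adjusted p = 0.139 with an estimated correlation). Creld2 differed by -0.73 ± 0.10 and Pdia4 by -0.94 ± 0.11. Of the hypertrophy genes, 3 of 15 members were higher and 6 lower (3 and 7 adjusted over the list alone). The members' median log2 fold change was -0.14 (camera adjusted p = 0.0140, and adjusted p = 0.250 with an estimated correlation). Rcan1 (-0.95 ± 0.083) and the metallothionein gene Mt1 (-0.73 ± 0.040) were lower. Of the interferon-stimulated genes, 0 of 22 members were higher and 3 lower (0 and 3 adjusted over the list alone). The median over the list was -0.16 (camera adjusted p = 0.000343, and adjusted p = 0.139 with an estimated correlation). B2m differed by -0.66 ± 0.038 and Rsad2 by -0.57 ± 0.062. All 3 lymphocyte markers were lower (3 adjusted over the list alone). Over these genes the median was -1.50 (camera adjusted p = 2.2e-05, and adjusted p = 0.139 with an estimated correlation). Without a filter on dim genes the median was -0.20 (adjusted p = 0.00325). Ighm differed by -2.52 ± 0.12 (-2.82 to -1.77 over the alternatives, depending on the offset).

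Of the fatty acid oxidation genes, 1 of 26 members was higher and 4 lower (1 and 5 adjusted over the list alone) in RKIP-labelled hearts. The list had a median of -0.048 (camera adjusted p = 0.0151, and adjusted p = 0.250 with an estimated correlation). Pdk4 stood at 4806 ± 80.5 against 11370.4 ± 362. Of the lipid synthesis genes, 3 of 20 members were higher and 6 lower (4 and 8 adjusted over the list alone). The list's median log2 fold change was -0.085 (camera adjusted p = 0.0445, and adjusted p = 0.280 with an estimated correlation). Mgll, a monoglyceride lipase gene, differed by -0.69 ± 0.053 and Agpat2 by 0.76 ± 0.072. White adipocyte markers were lower beside them: 1 of 7 members was higher and 2 lower (1 and 3 adjusted over the list alone). The members' median log2 fold change was -0.34 (camera adjusted p = 0.0140, and adjusted p = 0.250 with an estimated correlation). Car3 and Adipoq differed by -1.67 ± 0.070 and -1.52 ± 0.18, the latter depending on the offset (-1.85 to -0.92 over the alternatives). Of the sarcomere genes, 1 of 17 members was higher and 0 lower (1 and 0 adjusted over the list alone). The median over the list was 0.063 (camera adjusted p = 0.00545, and adjusted p = 0.463 with an estimated correlation). Of the oxidative phosphorylation subunits, 2 of 43 members were higher and 2 lower (2 and 2 adjusted over the list alone). Over these genes the median was 0.051 (camera adjusted p = 0.0301, and adjusted p = 0.560 with an estimated correlation). It ran from 0.010 to 0.058 over the alternatives, and the sarcomere median from 0.026 to 0.073. A filter at the 75th percentile ended the calls of the hypertrophy, fatty acid, lipid, adipocyte and oxidative phosphorylation lists, and quantile normalization, the shift to one median and a variance without trend each ended those of the sarcomere, lipid and oxidative phosphorylation lists. The lipid call was also lost without a filter on dim genes and without RKIP array 2 or GRK-Inh array 1 and the oxidative phosphorylation call without RKIP array 1 or either GRK-Inh array. Without RKIP array 2 the medians of the hypertrophy and fatty acid lists were -0.077 and -0.027. The hypertrophy median was -0.041 without a filter on dim genes, and the adipocyte median -0.15 with an offset of 200 (-0.40 to -0.039 over the alternatives). Of 33 lists, 22 did not pass by camera (adjusted p of 0.0868 and above).

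The receptor signalling list did not pass between the lines: 1 of 19 members was higher and 3 lower (1 and 3 adjusted over the list alone), camera adjusted p = 0.566. The RAF-MEK-ERK list did not pass either: 1 of 13 members was higher and 2 lower (1 and 2 adjusted over the list alone), adjusted p = 0.443. Dusp6 was lower (-0.66 ± 0.066) and Phlda1 higher (0.70 ± 0.051) in the RKIP-labelled hearts. Dbp was higher in the RKIP-labelled hearts (6996 ± 158 against 3797 ± 55.5) and Nfil3 lower (-0.88 ± 0.11), with the clock list not past camera's threshold (adjusted p = 0.327, and fry adjusted p = 0.0499, upwards). With the correlation between genes estimated from the data, camera called 0 of 33 lists in each comparison. By that test 5, 8 and 6 lists had an unadjusted p under 0.05 in the RKIP, GRK-Inh and direct comparisons, where fry called 16, 15 and 15. A list's median, mean and camera direction differed in sign for 6, 2 and 4 lists of the comparisons, none of which camera called at the preset correlation. Leaving out 1 array gave 542 genes without RKIP array 1, 527 without RKIP array 2, 465 without GRK-Inh array 1 and 515 without GRK-Inh array 2. A variance without trend gave 255 genes.

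**Figure D5:**
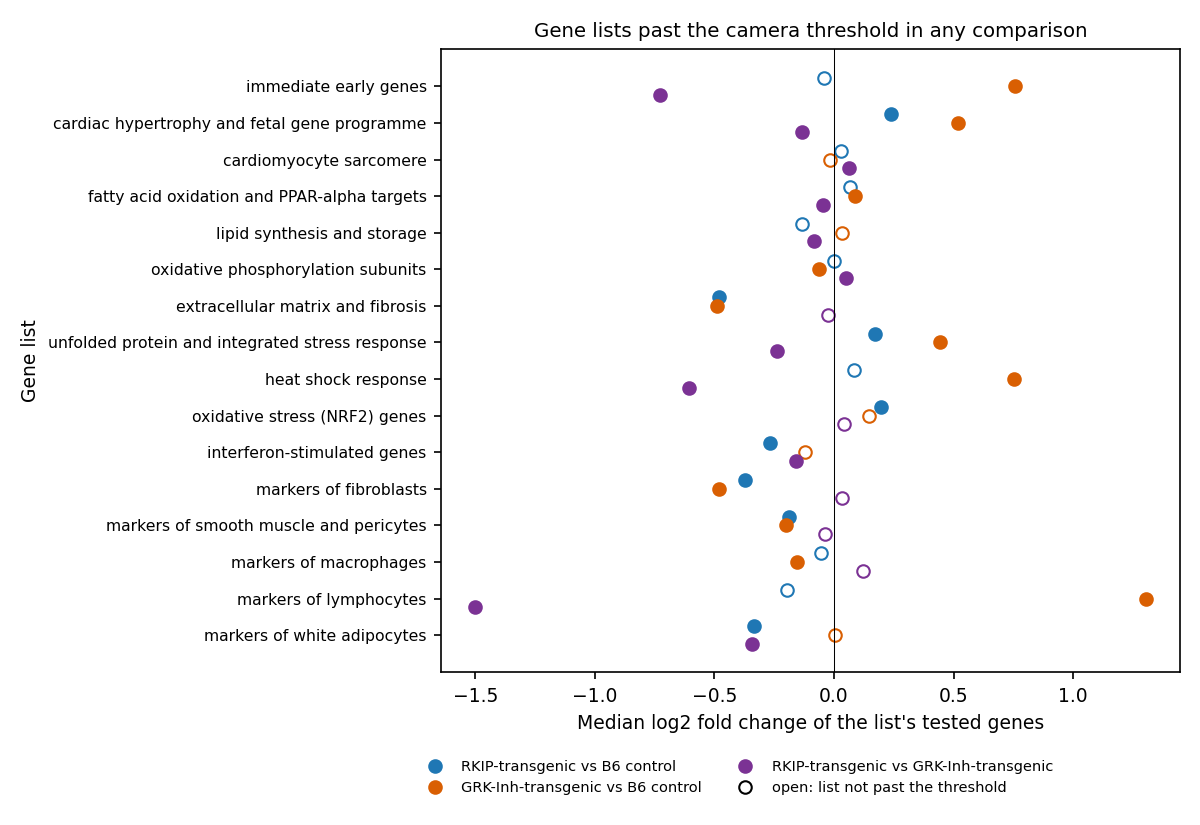
Median log2 fold change of the fixed gene lists that passed camera's threshold in any of the 3 comparisons, with filled points for lists past camera's threshold at the preset correlation of 0.01. Heat shock genes had medians of 0.75 in GRK-Inh hearts against control and -0.61 in RKIP-labelled against GRK-Inh hearts, and no filled list kept its call with an estimated correlation.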

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

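The tests of the simulated covariance, of scaling, of the time of day, of macrophages and of the fibroblast share were chosen after the result was seen. Probe sets with no gene in the table used gave signals that no gene-level comparison covers: of 2207 past the filter, 95 were called between RKIP-labelled and control hearts, 144 between GRK-Inh and control hearts, and 84 between the lines. An unnamed probe set had mean signals of 2671 in GRK-Inh, 797 in RKIP-labelled and 498 in control hearts. Of 541 probe sets with several symbols, which are not named here, 33 were higher and 39 lower in GRK-Inh than in control hearts, with log2 fold changes up to 2.70 and down to -2.32. In RKIP-labelled hearts 21 of them were higher and 38 lower than in controls. No explanation was tested for these. The labels name no B6 substrain, so strain variants, such as differences in copy number, stay open for them.

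A difference between the groups was also seen in 31 genes called in opposite directions in the lines and in 11 fixed lists past the threshold between the lines. With an estimated correlation none of these lists passed (lowest adjusted p = 0.0634, for the heat shock genes). All 31 genes passed in the direct comparison, 9 higher and 22 lower in the RKIP-labelled hearts. Calls in opposite directions against the same controls make this nearly certain, so it adds no evidence. Serpinh1 was chosen after its values were seen. Egr1 changed by -1.07 in RKIP-labelled and 1.47 in GRK-Inh hearts, Serpinh1 by -0.86 and 0.29, Pdk4 by -0.89 and 0.35, and Ptgds by 0.65 and -0.32. For Ighm, which is among the 31, another probe set was called in the other direction in the RKIP-labelled hearts. The list with the lowest camera p between the lines was that of the heat shock genes, at a median of -0.61.

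Genes moved together in both lines against the controls, with 590 called in the same direction. Of the 590 calls, 302 (51.2%) remained without B6 array 2 and 310 (52.5%) without B6 array 1, narrowly past the limit set beforehand. The 590 genes were called with both controls, and all 1219 and 1477 calls against control had arrays that did not overlap. The test therefore cannot exclude a single odd control array. The retained signs are no evidence, since the remaining control is still shared. Control hearts in a less mature state could not be excluded, because growth genes not seen before had medians of -0.21 in RKIP-labelled and -0.097 in GRK-Inh hearts, where their camera p was 0.0199 and 0.456, and their camera p with an estimated correlation was 0.0879 and 0.483. Chance values of the shared controls stay open: the covariance of the lines was 0.0369, against 0.00988 at most in 100 simulations, but these used the spread between arrays of a group, which can be technical, and leave out differences between control animals. An effect common to both transgenes, or a difference in breeding, handling or RNA quality between control and transgenic mice, stays open, since the design holds a single control group, whose actin ratios of 3.25 and 3.11 lay above those of the 4 transgenic arrays (2.92 to 3.03).

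In GRK-Inh hearts 10 of 13 heat shock genes and 13 of 19 immediate early genes rose (adjusted p = 0.0571 for each list with an estimated correlation). Scaling is argued against, as their median rise kept at least 98.7% of its size under the other scalings, and an admixture of macrophages is argued against by markers with a median of -0.15 and 0 members called upwards, although 2 of 3 lymphocyte markers rose. Another time of day of dissection remains a candidate explanation: the clock genes of opposite loops, 4 morning and 6 evening genes, moved apart by 0.85 on the log2 scale in GRK-Inh against control hearts (means 0.60 and -0.24, exact permutation p = 0.00476 over 210 arrangements, two-sided, the smallest they can give), against 0.18 in RKIP-labelled hearts (p = 0.390). Of the clock list, 0 of 15 members rose and 2 fell in RKIP-labelled hearts (Nr1d1 -0.55 and Dbp -0.22, camera adjusted p = 0.729 for the list). In GRK-Inh hearts Nr1d1 (-0.28) was not called. Genes are not independent replicates, and no test of the loops' difference between the lines was made. A change of the clock and of stress genes by the peptide inhibitor itself, or stress at dissection, stays open.

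Of 27 matrix genes, 14 fell and 1 rose in RKIP-labelled and 15 fell and 1 rose in GRK-Inh hearts (adjusted p = 0.168 and adjusted p = 0.112 with an estimated correlation). Scaling is argued against, since the median fall of the called members kept at least 91.8% of its size in both lines under the other scalings. A lower share of fibroblasts cannot be told apart from lower collagen expression: the mean of collagen genes less that of other fibroblast markers was -0.21 in GRK-Inh hearts (means -0.70 and -0.49, exact permutation p = 0.186) and -0.43 in RKIP-labelled hearts (means -0.77 and -0.34, p = 0.0134), and genes are not independent replicates. A lower share of these cells was therefore neither shown nor excluded for the GRK-Inh hearts. In the RKIP-labelled hearts the collagen genes, which included the basement membrane gene Col4a1, fell further than the other markers. No test of the difference between the lines was made for this contrast. A biological effect of either transgene on fibroblasts was not tested.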

How the results depend on the processing

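Of 386 calls of single genes, 205 held under every alternative in which the gene was tested, the other thresholds left out. Over 418 results and 7031 alternative values, 6175 stayed on their side of the threshold in the same direction, 846 lost and 10 gained a call, and 0 reversed. Leaving out an array ended 144 of the 386 calls at least once, where the lone array of a group is assumed to vary like the other groups. Leaving out each array in turn gave 621 to 1126 genes (RKIP against control, 1219 with all), 896 to 1483 (GRK-Inh against control, 1477), 465 to 874 (between the lines, 993) and 336 to 416 (same direction in both lines, 590), and a correlation of the lines of 0.51 to 0.62 (0.557). Lists past the threshold then numbered 7 to 11, 8 to 11 and 9 to 11. Fewer samples leave fewer degrees of freedom by construction. A variance without trend gave 297, 731, 255 and 161 genes in the same order, and the cause was not tested. No filter gave 617 genes between the lines, where more dim genes enter the adjustment. By construction of the threshold, an adjusted p under 0.1 gave 2243, 1508 and 894 genes in the GRK-Inh, direct and shared results, and a 2-fold minimum gave 41, 69, 44 and 18. All probe sets tested one by one gave 2324 calls for GRK-Inh against control, as more features were tested. Shifting the arrays to one median changed the percentages of higher calls to 57.3, 60.7, 39.9 and 62.7, from 49.1, 44.6, 50.7 and 48.6. The values give no background, so for genes near the filter level of 50.2 the part of the signal over background is unknown.

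With an estimated correlation camera called 0 lists in each comparison (8, 11 and 11 at the preset correlation). For the heat shock, hypertrophy and interferon lists the estimates were 0.0095, 0.0046 and -0.016, below the preset 0.01. A higher correlation therefore does not account for the loss of these calls, which is no evidence that correlation undoes them. With an estimated correlation camera takes its p-value from the 3 residual degrees of freedom, unlike at the preset one. The unadjusted p of the heat shock list in GRK-Inh hearts was 2.0e-21 at the preset and 0.00244 at the estimated correlation. A shifted list of simulated, independently drawn genes also went from an adjusted p of 2.3e-43 to 0.0274. No other cause was tested. For the RKIP comparison fry called 16 lists and all probe sets tested one by one 16, and a filter at the 75th percentile left 5 lists between the lines, and the cause was not tested. The fatty acid oxidation list in RKIP-labelled hearts reversed under fry (median 0.066, fry direction downwards, adjusted p = 0.0158), and the cause was not tested. Robust moderation has no counterpart in camera and was not run for lists. With the replicate number as a block (replicate block), 1150, 1434, 905 and 569 genes were called. The numbers do not pair the samples: deviations of arrays of like number correlated across genes at 0.026, -0.030 and -0.035.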

Other observations

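Tfrc, Cyp26b1 and Lrat were among the largest shared falls. Tfrc had signals of 1754 in RKIP-labelled and 1195 in GRK-Inh hearts against 7403 in controls. Cyp26b1, which degrades retinoic acid, and Lrat, which stores retinol as esters, had signals of 258 and 197 in controls, 40.5 and 44.2 in RKIP-labelled and 21.8 and 13.8 in GRK-Inh hearts.

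The growth regulators Igf2 and Plagl1, which are imprinted, fell in both lines as well. Igf2 had signals of 333, 309 and 824 in RKIP-labelled, GRK-Inh and control hearts, and Plagl1 fell by 0.70 and 1.13 on the log2 scale. Plagl1 and the further genes of this paragraph were chosen after their values were seen. Peg3 fell by 0.50 and 0.52, Ndn by 0.49 and 0.71 and Cdkn1c by 0.34 and 0.79, while Impact rose by 0.46 and 0.48. Of 16 growth genes that decline after birth and were not seen before the list was written, 3 fell and 1 rose in each line, and the others did not pass. The collagen chaperone gene Serpinh1 moved with the collagens in RKIP-labelled hearts (-0.86 ± 0.051) and against them in GRK-Inh hearts (0.29 ± 0.051).

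The tests of iron and retinoid genes were planned after the falls of Tfrc, Cyp26b1 and Lrat were seen and before the values of the other members were. A change of iron handling may go with the lower Tfrc, and the test of 13 other iron genes for a shift one way could not decide it, because genes of iron uptake and export can move in opposite directions. Its directional fry p was 0.921 in GRK-Inh and 0.177 in RKIP-labelled hearts, while fry's test for change in either direction gave 0.000242 and 0.000138. The latter makes no comparison with other genes and does not set the iron genes apart. By it the RAF-MEK-ERK list in GRK-Inh hearts had 2.7e-05 and the immediate early list in RKIP-labelled hearts 2.3e-06, though neither passed by camera. The iron exporter gene Slc40a1, named after its values were seen, rose by 0.58 in RKIP-labelled and 0.70 in GRK-Inh hearts on the log2 scale. Lower retinoid turnover and response may go with the falls of Cyp26b1 and Lrat, but the 9 other retinoid genes did not pass as lower: their camera p was 0.733 in RKIP-labelled and 0.484 in GRK-Inh hearts, with medians of 0.050 and 0.067. Of these 9, 1 was called higher and 0 lower in RKIP-labelled hearts, and 2 higher and 1 lower in GRK-Inh hearts. Both hypotheses stay open.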
